A study of Mus musculus with 12 samples.

How the data were processed

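R1 mouse embryonic stem cells grown on gelatin in medium with LIF were transfected for 48 h with control or Krr1 siRNAs, per the labels' protocols. Each lysate was divided equally between rRNA-depleted RNA-seq of fragments of 40 to 60 nt and ribosome profiling of footprints of about 30 nt, and both were sequenced as 50-base single-end reads on an Illumina HiSeq instrument, per the labels' protocols. The 12 libraries fall into 3 controls (siGFP, siNC, Lipo) and 3 Krr1 knockdowns per assay. The knockdown columns of the deposited tables carry the letters A, C and D while the GEO titles number them 1 to 3, so the columns were assigned to their group and assay but not to single titles. The control named Lipo is counted as a control, as its label gives it, although its name does not state an siRNA.

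The deposited tables hold raw counts of uniquely aligned reads per gene symbol, made by the authors with STAR and HTSeq on mm10, per the submitters' processing notes. The versions, the annotation, the strand setting and the trimming are not given in the sources used here. It was checked that the deposited count values are whole numbers whose gene entries add up to the total in the same table. Reads on no gene or on more than 1 gene stood at the end of each table and were kept out of library sizes and tests. Of 46512840 to 59073927 unique alignments per RNA library, 66.4% to 68.6% were on genes, 31.2% to 33.4% on no feature and 0.187% to 0.206% ambiguous. Of 52651807 to 68587565 unique alignments per footprint library, 36.6% to 42.4% were on genes, 57.5% to 63.3% on no feature and 0.0649% to 0.0725% ambiguous. The total on genes per library, given in the report, is the library size, and the 10 most abundant genes took 6.72% to 7.96% of it in RNA and 8.52% to 10.4% in footprints. Of 23420 symbols, 23260 (99.3%) matched the reference gene table (assembly GRCm38.p6, the build also named mm10), which gave gene types and coordinates. No genome came with the series, so no check of GC content or gene length was made. No pair of libraries of the same assay and condition was a duplicate: the chi-square per degree of freedom between them was 4.03 to 28.7. Pairs of a control and a knockdown library were not checked.

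Genes were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors (0.984 to 1.04 in RNA, 0.988 to 1.02 in footprints) and genes kept by filterByExpr, and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. The biological coefficient of variation was 11.0% in RNA and 9.30% in footprints. At an unadjusted p under 0.05 there were 2937 genes in RNA, where 702 are expected by chance, and 2984 in footprints, where 664 are expected. Standard errors of log2 fold changes were taken from the F statistic. Translational efficiency was the interaction of assay and condition in 1 model over the 12 libraries, without the lysate as a block, and with it as an alternative. The pairing comes from the labels, which state that each lysate was divided, and from the shared letters or names of the columns. It was checked on 6119 genes with a mean of at least 20 CPM: deviations from the group means correlated between the 2 assays of a lysate with r from 0.265 to 0.713, and in each lysate this was above the correlation with the other lysates of the same condition.

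Gene lists were tested with camera with a preset correlation between genes of 0.01, with camera with an estimated correlation and with fry, adjusted over the lists of a comparison, where at least 5 members were tested. Camera asks whether a list moved relative to other genes and fry whether it moves on balance in 1 direction. The mixed form of fry asks whether genes of a list change in either direction. The 26 lists covered ribosome assembly and ribosomal proteins, polymerase I, TOP mRNAs, snoRNA hosts, pluripotency and lineage markers, p53, ATF4, unfolded protein, heat shock and interferon responses, histones, cell cycle, glycolysis and cholesterol synthesis. The remaining 2 could not be tested: 2 members of the two-cell-like list passed the filter in RNA and 1 in footprints, and the 13 mitochondrially encoded genes were not analysed here. The SRF and YAP lists of the closing section were written after the largest changes were seen. Small- and large-subunit ribosomal protein genes were compared by an exact permutation test on the difference of their mean log2 CPM (prior count 2) per library.

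The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Krr1, then up to 10 called genes with the largest rise and fall per comparison, with no overlap between groups, a mean of at least 5 CPM and an established symbol, then up to 4 called members per list with the smallest adjusted p (or 2 abundant members where none was called), and 11 pluripotency and p53 pathway genes. Of the genes it names, 2 are not reported here. Genes outside it are marked in the report as chosen after their values were seen. The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, library totals without TMM factors, no low-count filter, a filter of at least 5 CPM in 3 libraries, small RNA genes left out, all 12 libraries in 1 fit, TMM factors over all 12 libraries, the lysate block, each library left out in turn and an estimated correlation between genes. The code was tested on simulated data with 100 genes changed by each of 2 fold sizes. The changed genes were drawn from those above 5 CPM in both assays. All counts were drawn independently, so the 2 assays of a lysate shared no deviations, and TE was fitted without the block. For RNA (13078 genes) 76% were recovered at 1.5-fold and 99% at 2-fold, with 16 false among 191 calls. For footprints (12988 genes) these were 85% and 99%, with 15 false among 199, and for translational efficiency (12976 genes) 58% and 95%, with 12 false among 165. In a simulated RNA comparison (14038 genes) with the G2/M list raised 1.3-fold, that list was called and 0 of the others among 24 lists. Its genes were drawn independently of each other, so it does not test for false list calls that come from correlation between genes. Where ribosomal protein or histone genes share reads with near-identical copies, and where genes overlap on either strand, the counts are uncertain.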

Results

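R1 mouse embryonic stem cells were transfected for 48 h with control siRNAs or with siRNAs against Krr1, an assembly factor of the small ribosomal subunit that acts in the small-subunit processome, the nucleolar complex in which pre-ribosomal RNA is first processed. Per the labels, 3 different control siRNAs and 3 different Krr1 siRNAs were used. The control libraries carry the names siGFP, siNC and Lipo, and the knockdown libraries are called here siKrr1 A, siKrr1 C and siKrr1 D. Each lysate was divided between RNA-seq and ribosome profiling, which sequences the mRNA fragments protected by ribosomes (footprints, RPF). This gave 12 libraries, 3 per group and assay. Reads counted on genes numbered 37934900, 39670139 and 35795829 in the RNA libraries siGFP, siNC and Lipo and 31318772, 37673764 and 36528200 in siKrr1 A, C and D. The footprint libraries held 22317119, 28026444 and 24729948 counts in the controls and 21615934, 23718373 and 28911254 in siKrr1 A, C and D. The labels do not state whether the samples were separate cultures, so the p-values below measure only the spread between these samples, which per the labels received different siRNAs, although the name Lipo states none. Levels are relative to the other RNAs of the same library, not per cell. For each gene described below as risen or fallen in RNA or footprints, the 3 knockdown libraries all lay on the same side of the 3 controls.

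Krr1 (chromosome 10, 111972695 to 111988430, mm10) was lower in each of the 3 knockdown lysates. Its RNA stood at 21.7% of the control mean in siKrr1 A, 37.3% in siKrr1 C and 41.5% in siKrr1 D, a group mean of 33.5% ± 10.4 (SD, n = 3), while the controls varied by 2.87% (SD, n = 3). Scaled to library size (CPM), Krr1 RNA was 156 ± 4.46 in controls and 52.1 ± 16.3 in knockdown cells. Krr1 footprints were at 18.9%, 37.5% and 31.4% of the control mean in siKrr1 A, C and D, with a mean of 29.3% ± 9.45 (SD, n = 3). The log2 fold change was -1.58 ± 0.18 (SE) in RNA (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00228). In footprints it was -1.77 ± 0.18 (edgeR adjusted p = 0.000819). Both calls held with each library left out in turn.

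**Figure D1:**
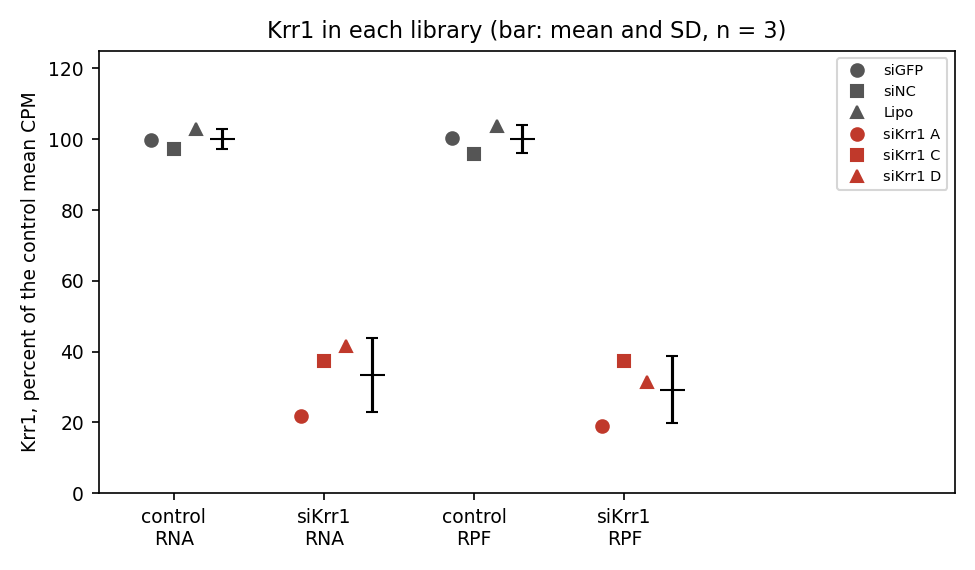
Krr1 level in each library as a percentage of the control mean CPM of its assay, for RNA and footprints (RPF); symbols are single libraries, and the bar beside each group is the mean with its SD (n = 3). The knockdown libraries lie between 18.9% and 41.5%.

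The first comparison asked which mRNAs changed in level after loss of Krr1. The largest rise in RNA among the named genes was in Tagln (transgelin, an actin-binding protein), with a log2 fold change of 3.01 ± 0.67 (SE), from 2.22 ± 0.536 to 18.1 ± 20.6 CPM (SD, n = 3). Myl9, a regulatory myosin light chain, rose by 2.63 ± 0.53 and the matricellular gene Cyr61 by 1.71 ± 0.29. The lysophosphatidic acid receptor Lpar6 (1.47 ± 0.17), the annexin Anxa3 (1.47 ± 0.23), the VEGF receptor Kdr (1.49 ± 0.29), Tinagl1 (1.35), the tight-junction protein Cldn6 (1.34), the ephrin receptor Epha1 (1.33) and the secreted protease inhibitor Serpine2 (1.32) rose as well. The largest falls were in Vax2, a homeobox factor of the ventral eye (-2.34 ± 0.24), and Zbtb7c, a zinc-finger protein (-1.66 ± 0.18). Slc11a1 (-1.48), Xaf1 (-1.39), Mapt (tau, -1.35), Padi4 (-1.33), the amino acid transporter Slc38a5 (-1.33), Islr2 (-1.30) and the galectin Lgals3 (-1.28) followed. The edgeR adjusted p of these genes ran from 0.00169 for Vax2 to 0.0377 for Serpine2. With a library left out in turn, the calls of Lpar6, Anxa3, Cldn6, Epha1, Vax2, Zbtb7c, Padi4, Islr2 and Lgals3 were kept. Tagln was at 41.9 CPM in siKrr1 A but at 7.29 and 5.25 CPM in siKrr1 C and D, and its log2 fold change was 1.49 without siKrr1 A, as that of Myl9 was 1.54 and that of Serpine2 0.78. Its edgeR adjusted p reached 0.118 without siGFP, and that of Myl9 0.109 without siGFP, of Cyr61 0.0699 and of Tinagl1 0.0632 without siGFP, of Kdr 0.0751 and of Serpine2 0.134 without Lipo. Among the falls it reached 0.132 for Slc11a1, 0.077 for Xaf1, 0.105 for Mapt and 0.117 for Slc38a5, each without siGFP.

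In total 378 genes were higher and 296 lower in RNA among 14038 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 78 were higher and 63 lower by more than 2-fold. The counts depended on the libraries. Without siGFP, siNC or Lipo, 66, 78 and 63 genes were higher and 57, 60 and 51 lower. Without siKrr1 A, C or D, 174, 759 and 222 were higher and 133, 539 and 166 lower. No called gene changed its direction in any of these fits. A gene without overlap between the groups could hardly do so, which makes this a weak check.

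Several genes of the naive pluripotent state fell in RNA, while the core factors Pou5f1 and Sox2 were not called. Of 34 tested members of the naive and core pluripotency list, 8 fell and 1 rose, and adjusted over the list alone 12 fell and 5 rose. Without siGFP, siNC or Lipo 3, 2 and 2 fell, and without siKrr1 A, C or D 4, 13 and 5. Tbx3, a T-box factor of the naive network, fell by 1.08 ± 0.11 (SE), from 84.1 ± 3.7 to 39.8 ± 6.95 CPM (n = 3; edgeR adjusted p = 0.00169). Nanog fell by 0.58 ± 0.09, from 449 ± 4.35 to 299 ± 38.4 CPM (edgeR adjusted p = 0.00758). Tfcp2l1 (-0.62), Klf4 (-0.61), Klf2 (-0.61), Tcl1 (-0.50), Zfp42 (-0.43) and Esrrb (-0.36) fell too, and the LIF co-receptor Il6st rose by 0.33; Klf2, Tcl1 and Il6st were chosen after their values were seen. Pou5f1 was at -0.13 ± 0.09 (edgeR adjusted p = 0.453) and Sox2 at 0.03 ± 0.08 (0.876). The Tbx3 and Nanog calls held with each library left out, whereas the edgeR adjusted p reached 0.107 for Klf4, 0.0824 for Tfcp2l1 (both without siGFP), and, without Lipo, 0.105 for Esrrb, 0.111 for Zfp42, 0.103 for Klf2, 0.108 for Tcl1 and 0.186 for Il6st. As a set the list was lower than other genes (camera adjusted p = 0.000636; adjusted p = 0.437 with an estimated correlation).

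Markers of later lineages moved in both directions. Of 13 primed epiblast genes, 3 rose and 1 fell (7 and 2 when adjusted over the list alone). Otx2, a factor of the formative epiblast, rose by 1.27 ± 0.20, Lef1 by 1.41 and the DNA methyltransferase Dnmt3b by 0.34, and Fgf15 fell by 0.76. Among 14 endoderm genes the matrix genes Sparc (0.47), Lamb1 (0.45) and Col4a1 (0.48) rose and Apoe fell by 0.97 ± 0.10, from 617 ± 65.4 to 314 ± 33.3 CPM (4 and 1 over the list alone). Among 12 neural genes Nes rose by 0.85 and Neurod1 by 1.39, while the neuronal tubulin Tubb3 fell by 0.82 (3 and 1 when adjusted over the list alone). Of 13 trophectoderm genes, Krt7 (2.57, from 0.106 to 0.658 CPM), Krt18 (0.46) and Wnt7b (0.90) rose and Gata2 fell by 1.15 (5 and 3 over the list alone). Kdr was the called member among 13 mesoderm genes (1 over the list alone), and Tagln and Col5a2 (1.36) were those among 14 fibroblast and feeder genes (2 over the list alone). The camera adjusted p was 0.0716 for primed epiblast, 0.647 for mesoderm, 0.343 for endoderm, 0.236 for neural ectoderm, 0.178 for trophectoderm and 0.236 for fibroblast genes. None of these lists was therefore called as a set by camera. The primed list was called without siGFP (camera adjusted p = 0.0354; adjusted p = 0.492 with an estimated correlation). Without a control library at most 1 gene rose and 1 fell in each of these 6 lists. Without siKrr1 A or D at most 2 rose and 1 fell, and without siKrr1 C 5 primed genes rose and 2 fell. The mixed form of fry allows changes in either direction. Its adjusted p was 0.0145 for primed epiblast and trophectoderm, 0.0338 for mesoderm, 0.00607 for endoderm and neural ectoderm and 0.139 for fibroblast genes. It was also low for polymerase I (0.0161) and glycolysis genes (0.0338), lists without a called member. A low value is thus not particular to lineage lists. The calls of Otx2, Apoe and Tubb3 held with each library left out; the highest edgeR adjusted p of the other lineage genes then lay between 0.0639 for Neurod1 (without Lipo) and 0.175 for Wnt7b (without Lipo).

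Targets of the transcription factor p53 rose. Of 38 tested, 21 rose and 1 fell (28 and 2 when adjusted over the list alone), with a median log2 fold change of 0.60. Without siGFP, siNC or Lipo 5, 4 and 4 rose, and 10 without siKrr1 A or siKrr1 D. Plk2 rose by 1.17 ± 0.18, Phlda3 by 1.06 ± 0.14, the receptor gene Eda2r by 0.94 ± 0.10 and the cyclin Ccng1 by 0.85 ± 0.14, with edgeR adjusted p of 0.00799, 0.004, 0.00227 and 0.0101. The cell cycle inhibitor Cdkn1a rose by 0.69 ± 0.15 (edgeR adjusted p = 0.0301) and Mdm2, the ubiquitin ligase of p53, by 0.63 ± 0.13 (0.0249), but these values reached 0.128 and 0.105 without Lipo. The apoptosis genes Pmaip1 (1.24), Perp (1.07) and Apaf1 (0.60) also rose, and the member that fell was the glycolytic regulator Tigar, listed as 9630033F20Rik (-0.41). These 4 were chosen after their values were seen, and their edgeR adjusted p reached 0.0917 without siGFP for Pmaip1 and 0.0591, 0.135 and 0.161 without Lipo for Perp, Apaf1 and 9630033F20Rik. The calls of Plk2, Phlda3, Eda2r and Ccng1 held with each library left out. Trp53 RNA itself was at 0.24 ± 0.08 (edgeR adjusted p = 0.116). The set was called with the preset correlation (camera adjusted p = 2.43e-19; adjusted p = 0.437 with an estimated correlation). Its median over the list lay 0.83, 0.27 and 0.53 above the control mean in siKrr1 A, C and D, against 0.08 in the farthest control library.

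A part of the ATF4 and amino acid response genes fell. Of 32 ATF4 list genes 11 fell and none rose (16 and 1 when adjusted over the list alone; median -0.28). Without siGFP, siNC or Lipo 6, 3 and 2 fell, and 6 without siKrr1 A. Nupr1 fell by 1.16 ± 0.20, the mitochondrial enzyme Pck2 by 0.86 ± 0.13, Herpud1 by 0.65 ± 0.08 and Atf4 by 0.43 ± 0.08 (edgeR adjusted p = 0.0108, 0.00708, 0.00352 and 0.0135). Without Lipo the edgeR adjusted p was 0.0591 for Nupr1 and 0.0778 for Atf4. The ATF4 set was lower (camera adjusted p = 8.35e-12; adjusted p = 0.437 with an estimated correlation). Of 29 G1/S genes 3 fell and none rose (6 and 0 when adjusted over the list alone), namely the D-type cyclin Ccnd3 (-0.63), the polymerase clamp Pcna (-0.35) and the ribonucleotide reductase subunit Rrm2 (-0.33). Without siGFP, siNC or Lipo 0 of the G1/S genes were called with edgeR, and 1 without siKrr1 A and 6 without siKrr1 C. These calls were lost without single libraries, with edgeR adjusted p of 0.0979 for Ccnd3 without siGFP and 0.15 for Pcna and 0.13 for Rrm2 without Lipo. The G1/S set was lower (camera adjusted p = 8.56e-05; adjusted p = 0.437 with an estimated correlation), whereas the 30 G2/M genes had no called member (0 over the list alone; camera adjusted p = 0.647), with Top2a at 0.18 and Bub1b at -0.01. Myc RNA was at -0.35 ± 0.11 (edgeR adjusted p = 0.0868).

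Assembly factors of the ribosome showed little change in RNA. Among 59 processome and small-subunit maturation factors, Pwp2 rose by 0.29 ± 0.07 (0 over the list alone; camera adjusted p = 0.957). Among 51 large-subunit assembly factors, the SUMO protease Senp3 fell by 0.42 ± 0.09 (1 over the list alone; camera adjusted p = 0.919). None of 17 polymerase I genes was called (0 over the list alone; camera adjusted p = 0.647; 3 lower without siKrr1 C), with Rrn3 at 0.17 and Ubtf at -0.16. The median of the processome and polymerase I lists was above 0 and their mean below 0, and camera pointed up for the first and down for the second. The edgeR adjusted p of Pwp2 was 0.174 without Lipo and that of Senp3 0.118 without siGFP. Of 33 small-subunit ribosomal protein genes none was called (0 over the list alone; median -0.13), Rps3 standing at -0.05. Of 49 large-subunit genes Rpl22l1, a paralog of Rpl22, fell by 0.59 ± 0.08 (1 over the list alone; median -0.18; 3 lower without siKrr1 A and 2 without siKrr1 C). Both sets were called lower (camera adjusted p = 0.0121 for the small and 1.69e-05 for the large subunit; adjusted p = 0.545 and 0.437 with an estimated correlation). In the small-subunit list the lowest library was siKrr1 D, whose median lay at -0.35 against -0.01 in siKrr1 A and -0.04 in siKrr1 C, and without siKrr1 D the median log2 fold change of the list was -0.02 and the camera adjusted p 0.35. The large-subunit list stayed called without siKrr1 D, with a median of -0.09 (camera adjusted p = 0.00952; adjusted p = 0.561 with an estimated correlation). Reads of ribosomal protein genes can be shared with pseudogenes and those of histone genes with near-identical copies, so their values are uncertain.

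The remaining lists gave the following in RNA. Eif3f fell by 0.27 among 14 translation factors with 5-prime TOP mRNAs (1 over the list alone), and the set was lower (camera adjusted p = 0.0353; adjusted p = 0.437 with an estimated correlation). None of 13 snoRNA host genes was called (1 fell over the list alone), with Gas5 at -0.40 and Snhg1 at 0.14, and none of 24 cholesterol synthesis genes was called (0 over the list alone), with Sc4mol at -0.16. Both sets were called lower (camera adjusted p = 0.0353 each; adjusted p = 0.544 and 0.6 with an estimated correlation). These 3 calls depended on single libraries. The camera adjusted p was 0.0805 without Lipo and 0.228 without siKrr1 D for the TOP list. For the snoRNA hosts it was 0.0503 without siNC, 0.177 without Lipo and 0.265 without siKrr1 D, and for cholesterol synthesis 0.293 without siNC, 0.135 without siKrr1 A and 0.167 without siKrr1 D. Eif3f was called in none of the fits with a library left out, its edgeR adjusted p reaching 0.197 without Lipo. None of 60 replication-dependent histone genes was called (0 over the list alone), with Hist2h2bb at -0.09 and Hist1h1a at -0.26 (7 fell without siKrr1 C), and the set was lower (camera adjusted p = 2.94e-07; adjusted p = 0.437 with an estimated correlation). Of 15 interferon response genes the antiviral tetherin gene Bst2 rose by 0.66 and Xaf1 fell (1 and 1 over the list alone; camera adjusted p = 0.0951, and 0.00952 without siKrr1 D, where the adjusted p = 0.561 with an estimated correlation). The edgeR adjusted p of Bst2 was 0.068 without siGFP. The lists of 19 unfolded protein response genes (Calr -0.21, Canx 0.30), 16 heat shock genes (Hsp90ab1 -0.11, Hspa4 -0.20) and 25 glycolysis genes (Pkm 0.01, Slc2a3 -0.26) held no called member. Adjusted over the list alone, 1 unfolded protein response gene rose and 1 fell, and 0 of the others were called. Their camera adjusted p was 0.236, 0.236 and 0.227, and the glycolysis list was called lower without siGFP (0.0392) or Lipo (0.0234), with adjusted p = 0.58 and 0.585 with an estimated correlation. Of the 10 lists called in RNA with the preset correlation, 0 were called with an estimated correlation. The fry test for a move in 1 direction called no list in RNA. Its adjusted p was 0.106 for the p53, 0.0942 for the ATF4 and 0.109 for the G1/S list.

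**Figure D2:**
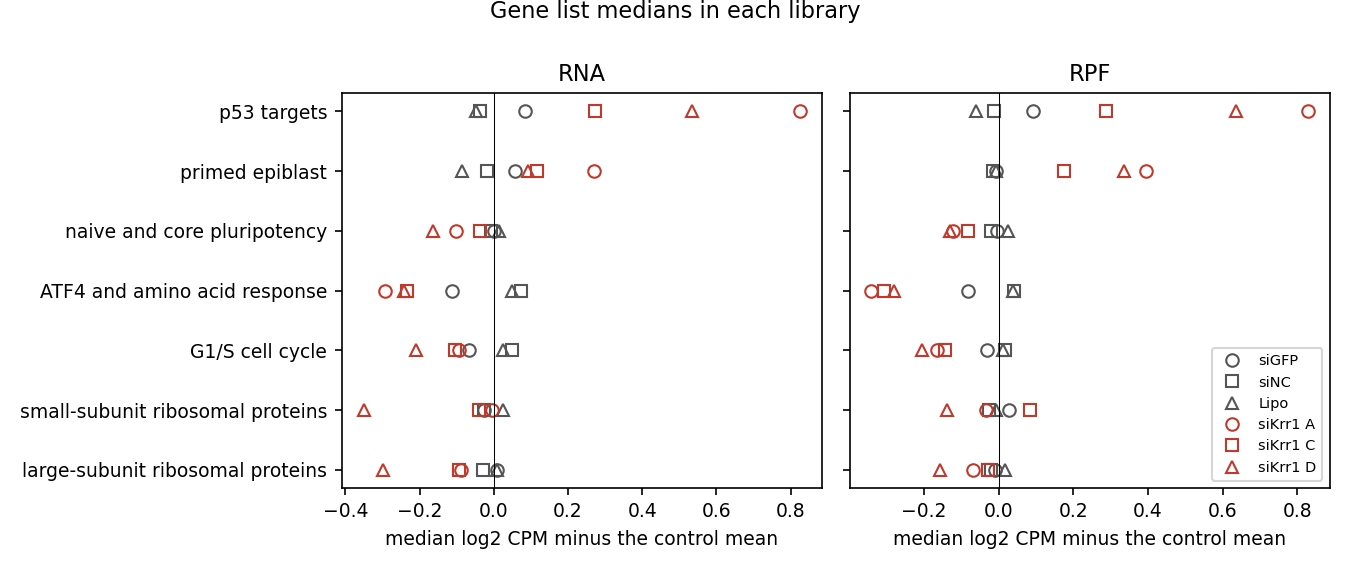
Median log2 CPM of 7 gene lists in each library, relative to the mean of the controls (horizontal axis), in RNA and footprints. The p53 list lies at 0.83, 0.27 and 0.53 in siKrr1 A, C and D in RNA, and the small-subunit ribosomal protein list is lowest in siKrr1 D in RNA (-0.35).

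The footprint comparison asked which genes changed in ribosome occupancy. The largest rises were again in Tagln (3.33 ± 0.70, SE) and Myl9 (2.66 ± 0.52), followed by the matricellular thrombospondin Thbs1 (2.00 ± 0.30), the Wnt effector Lef1 (1.79 ± 0.26), Cyr61 (1.71), Kdr (1.51), Lpar6 (1.45), Ctgf (1.42 ± 0.24), Cpne2 (1.42) and Serpine2 (1.40). Thbs1 footprints went from 2.23 ± 0.546 to 8.91 ± 3.73 CPM and those of Ctgf from 32.4 ± 1.39 to 86.8 ± 35.8 CPM (SD, n = 3). The largest falls were in Vax2 (-2.78 ± 0.29), Slc11a1 (-1.46), Xaf1 (-1.44), the GDNF-family co-receptor Gfra2 (-1.42), Slc38a5 (-1.41), the synaptic scaffold Dlgap3 (-1.35), the myosin Myo1f (-1.35), Lgals3 (-1.29) and the calcium pump Atp2a3 (-1.27). The edgeR adjusted p of these genes ran from 0.000378 for Dlgap3 to 0.0277 for Slc11a1. Without single libraries the calls of Thbs1, Lef1, Lpar6, Cpne2, Vax2, Xaf1, Gfra2, Dlgap3, Myo1f, Lgals3 and Atp2a3 were kept. The edgeR adjusted p reached 0.0997 for Tagln, 0.0907 for Cyr61, 0.121 for Kdr, 0.0554 for Ctgf and 0.123 for Serpine2 without Lipo, and 0.086 for Myl9, 0.115 for Slc11a1 and 0.0636 for Slc38a5 without siGFP. The log2 fold change was 1.83 for Tagln, 1.69 for Myl9 and 0.86 for Serpine2 without siKrr1 A, and 0.99 for Kdr without siKrr1 D.

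Footprint counts were higher for 450 and lower for 356 of 13287 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 84 and 46 beyond 2-fold. The share of higher among called genes was 55.8%, and with library totals in place of TMM factors it was 67.0% (579 higher and 285 lower). Without siGFP, siNC or Lipo, 130, 106 and 67 genes were higher and 116, 97 and 64 lower. Without siKrr1 C or D, 791 and 293 were higher and 546 and 256 lower.

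Naive pluripotency genes fell in footprints as well, 12 of 34 lower and 2 higher (16 and 6 when adjusted over the list alone; 4 lower without Lipo; 0 higher whichever control library was left out and 1 higher whichever knockdown library was). Tbx3 fell by 0.85 ± 0.09, Klf4 by 0.64 ± 0.06, Nanog by 0.60 ± 0.08 and Tcl1 by 0.56 ± 0.08 (edgeR adjusted p = 0.00134, 0.000817, 0.00335 and 0.00323), and these 4 calls held with each library left out. Tfcp2l1 (-0.59), Klf2 (-0.47), Prdm14 (-0.45), Fgf4 (-0.45) and Esrrb (-0.37) fell, and Fbxo15 (0.50) and Dppa4 (0.36) rose. Tfcp2l1, Klf2, Prdm14, Fgf4, Fbxo15 and Dppa4 were chosen after their values were seen. Without Lipo the edgeR adjusted p was 0.0502 for Esrrb, 0.0555 for Tfcp2l1, 0.0536 for Klf2, 0.0991 for Prdm14 and 0.0603 for Fgf4, and it reached 0.174 for Fbxo15 without siGFP and 0.171 for Dppa4 without siNC. Pou5f1 was at -0.22 ± 0.06 (edgeR adjusted p = 0.0557), Zfp42 at -0.28 ± 0.09 (0.0883) and Sox2 at 0.10 ± 0.06 (0.319). The set was lower (camera adjusted p = 7.61e-06; adjusted p = 0.265 with an estimated correlation). The fry test, which asks whether the genes of a list move on balance one way, gave an adjusted p of 0.0472, and of 0.0942 in RNA.

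Of 12 primed epiblast genes 5 rose and 2 fell in footprints (7 and 3 when adjusted over the list alone; 2 and 0 whichever control library was left out, 3 and 0 without siKrr1 D). Lef1, Otx2 (1.38 ± 0.16), the cadherin Cdh2 (0.83), Sox4 (0.61) and Dnmt3a (0.37) rose, and Fgf15 (-0.78) and Sox3 (-0.49) fell. Cdh2, Sox4 and Sox3 were chosen after their values were seen, and their edgeR adjusted p reached 0.113 without Lipo for Cdh2 and Sox4 and 0.141 without siGFP for Sox3. The set was higher (camera adjusted p = 0.00511; adjusted p = 0.233 with an estimated correlation). Apoe fell by 0.96 ± 0.08 while Sparc (0.39) and Lamb1 (0.38) rose among 13 endoderm genes (4 higher and 1 lower over the list alone). Tubb3 fell by 0.87 and Nes (0.85) and Neurod1 (1.27) rose among 12 neural genes (4 and 2 over the list alone). Kdr rose and Eomes fell by 0.57 among 13 mesoderm genes (3 and 1 over the list alone). Gata3 (1.87) and Fgfr2 (0.99) rose and Gata2 (-0.79) and Tead4 (-0.55) fell among 13 trophectoderm genes (7 and 3 over the list alone). Tagln, Col5a2 (1.22) and Bgn (1.59) rose among 15 fibroblast genes (3 over the list alone). The camera adjusted p was 0.976 for endoderm, 0.696 for neural, 0.778 for mesoderm, 0.115 for trophectoderm and 0.339 for fibroblast genes. The trophectoderm list was called without siGFP (0.0319) or siKrr1 C (0.0376), with adjusted p = 0.408 and 0.381 with an estimated correlation. Without a control library at most 1 gene rose and 1 fell in each of these 5 lists, and without siKrr1 C 5 endoderm, 4 trophectoderm and 2 mesoderm genes rose. Without siKrr1 D 0 trophectoderm genes rose. The mesoderm list had a median below 0 with a mean above 0 and camera pointing up, and the endoderm list a median above 0 and a mean below 0. The mixed form of fry gave an adjusted p of 0.00167 for endoderm, 0.00182 for neural and 0.0243 for mesoderm genes. For trophectoderm it was 0.00826 and for fibroblast genes 0.0631. It was also low (0.000134) for the polymerase I list, which had no called member. The calls of Lef1, Otx2, Apoe and Tubb3 held with each library left out; the highest edgeR adjusted p of the other lineage genes named by the rule then lay between 0.0553 for Nes (without siGFP) and 0.198 for Bgn (without Lipo).

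Of 37 p53 targets 21 rose in footprints and 0 fell (27 and 1 when adjusted over the list alone; median 0.63), and 11, 10 and 6 rose without siGFP, siNC or Lipo. Plk2 (1.33 ± 0.19), Phlda3 (1.15 ± 0.15), Tnfrsf10b (0.71 ± 0.09) and Zmat3 (0.63 ± 0.08) had edgeR adjusted p of 0.0035, 0.00255, 0.00284 and 0.00235, and kept their calls with each library left out. Mdm2 rose by 0.93 ± 0.15 and Cdkn1a by 0.80 ± 0.17, with edgeR adjusted p of 0.00705 and 0.0203 that reached 0.0558 and 0.107 without Lipo. Trp53 was at 0.24 ± 0.08 (edgeR adjusted p = 0.112). The set was higher (camera adjusted p = 2.62e-20; adjusted p = 0.313 with an estimated correlation; fry adjusted p = 0.131). Of 32 ATF4 list genes 15 fell and none rose (20 and 1 when adjusted over the list alone; 8 lower without siNC and 4 without Lipo), among them Herpud1 (-0.67), Atf4 (-0.62 ± 0.09), Mthfd2 (-0.50) and Psat1 (-0.45), which kept their calls with each library left out. The set was lower (camera adjusted p = 5.04e-15; adjusted p = 0.233 with an estimated correlation; fry adjusted p = 0.0406). Of 29 G1/S genes 7 fell (13 when adjusted over the list alone; 3, 2 and 2 without siGFP, siNC or Lipo and 4 without siKrr1 D), including Ccnd3 (-0.62), Rrm2 (-0.36), Cdc6 (-0.34) and the replicative helicase subunit Mcm4 (-0.23). The set was lower (camera adjusted p = 1.06e-09; adjusted p = 0.233 with an estimated correlation; fry adjusted p = 0.0194). The call of Rrm2 held, while the edgeR adjusted p reached 0.0508 for Ccnd3 without siGFP, and 0.0832 for Cdc6 and 0.136 for Mcm4 without Lipo. The mitotic genes Bub1 (0.35) and Cenpe (0.31) rose among 30 G2/M genes (2 over the list alone; camera adjusted p = 0.264). Their edgeR adjusted p reached 0.0769 without Lipo and 0.0826 without siGFP. Myc footprints fell by 0.26 ± 0.06 (edgeR adjusted p = 0.0282, and 0.11 without siGFP).

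Few ribosomal protein genes changed in footprints. Rps2 fell by 0.52 and Rps27l (0.41) and Rps24 (0.32) rose among 33 small-subunit genes (1 lower and 2 higher over the list alone; camera adjusted p = 0.778), and Rpl22l1 fell by 0.56 among 49 large-subunit genes (1 over the list alone). The large-subunit list had a camera adjusted p of 0.0823, which was 0.0458 without siGFP, 0.0188 without siKrr1 A and 0.0218 without siKrr1 C. There the adjusted p was 0.849, 0.903 and 0.63 with an estimated correlation, and 4 of its genes were lower without siKrr1 A. The processome factors Fcf1 (0.28) and Utp20 (0.22) rose among 59 (0 over the list alone; camera adjusted p = 0.804). Senp3 fell by 0.39 among 51 large-subunit assembly factors (1 over the list alone; camera adjusted p = 0.976). The polymerase I list had no call (0 over the list alone; camera adjusted p = 0.36), with Ncl at -0.04 and Nolc1 at -0.11. With a library left out, the highest edgeR adjusted p of these called genes lay between 0.0589 for Rpl22l1 and 0.174 for Utp20, both without Lipo. The small-subunit and TOP lists each had a median of -0.02, which was 0.01 with library totals in place of TMM factors. No gene of the TOP list was called (0 over the list alone; camera adjusted p = 0.804), with Gnb2l1 at -0.01 and Eef2 at 0.11. Among 13 snoRNA hosts 1500012F01Rik, the host gene Zfas1, rose by 0.34 (2 higher and 1 lower over the list alone; camera adjusted p = 0.791).

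Of 58 histone genes 5 fell in footprints (6 lower and 1 higher over the list alone; 1, 1 and 2 lower without siGFP, siNC or Lipo and 3 without siKrr1 D), with Hist1h2bm at -0.51, and the set was lower (camera adjusted p = 0.000781; adjusted p = 0.8 with an estimated correlation). Hspa5 (-0.32), Calr (-0.30) and Manf (-0.24), chaperones and a secreted factor of the endoplasmic reticulum, fell among 19 unfolded protein response genes (5 lower and 1 higher over the list alone; 1, 0 and 0 lower without siGFP, siNC or Lipo and 5 without siKrr1 C; camera adjusted p = 0.0823, 0.0268 without siGFP and 0.0341 without siKrr1 C, where the adjusted p was 0.832 and 0.63 with an estimated correlation). Sc4mol fell by 0.29 among 24 cholesterol genes (0 over the list alone), a set that was lower (camera adjusted p = 0.0122; adjusted p = 0.8 with an estimated correlation) but not without siNC (0.198) or siKrr1 A (0.0755). Bst2 rose by 0.62 and Xaf1 fell among 15 interferon genes (1 and 1 over the list alone; camera adjusted p = 0.0924, and 0.00453 without siKrr1 D, where the adjusted p = 0.249 with an estimated correlation). Hspa4 fell by 0.24 among 16 heat shock genes (2 lower and 1 higher over the list alone; camera adjusted p = 0.427) and the glucose transporter Slc2a3 by 0.32 among 25 glycolysis genes (2 lower and 1 higher over the list alone; camera adjusted p = 0.307). The calls of Hist1h2bm and Bst2 held with each library left out; the edgeR adjusted p reached 0.0709 for Hspa5, 0.0727 for Calr and 0.162 for Hspa4 without Lipo and 0.16 for Manf, 0.131 for Slc2a3 and 0.186 for Sc4mol without siNC. Of the 7 lists called in footprints, 0 were called with an estimated correlation.

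The third comparison asked whether translational efficiency (TE), the footprint level relative to the RNA level of a gene, changed. Zbtb7c stood out: its RNA fell from 7.71 ± 0.791 to 2.43 ± 0.431 CPM while its footprints were at 87.1 ± 12.4 CPM in controls and 83.4 ± 19.4 CPM in knockdown cells (SD, n = 3), and its TE was higher by 1.59 ± 0.25 (SE) on the log2 scale without being called (edgeR adjusted p = 0.191). With the lysate as a block it was called (log2 change 1.61 ± 0.17, edgeR adjusted p = 0.000297), as it was without siKrr1 A (1.71, edgeR adjusted p = 0.0268). Counts per gene do not say where reads lie, so whether translating ribosomes gave the Zbtb7c footprint reads was not tested. In the fit without the block edgeR called 0 of 13109 genes in either direction, with 302 at an unadjusted p under 0.05 where 655 are expected by chance. With fewer small p-values than chance gives, this fit is conservative, and the absence of calls does not show that TE was unchanged. It ignores the sharing of lysates, and its biological coefficient of variation was 10.2%, against 5.56% with the block. limma-voom called 0 genes and DESeq2 2, Zbtb7c (1.59) and the microRNA gene Mir1949 (1.47). With the lysate as a block, edgeR called 7 genes higher and 1 lower, with 931 at an unadjusted p under 0.05. Besides Zbtb7c these were Mir1949 (1.48), the small nucleolar RNA genes Snora7a (0.85), Snora64 (0.77) and Snord100 (0.63), the RNA polymerase II subunit Polr2a (0.49), the dynein heavy chain Dync1h1 (0.39) and the GTPase Rab6a (-0.72). These 8 genes were chosen after their values were seen. 4 of the 8 are small RNA genes, which make up 1.08% of those tested. Small RNAs are not translated, so a TE change has no plain meaning for them, and their reads may come from host genes.

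No named gene was called in TE without the block. The log2 TE change was -0.02 ± 0.13 (SE) for Nanog, -0.03 ± 0.15 for Klf4, -0.09 ± 0.11 for Pou5f1, 0.22 ± 0.16 for Tbx3, 0.29 ± 0.24 for Mdm2, 0.11 ± 0.26 for Cdkn1a and -0.20 ± 0.30 for Krr1. Ribosomal protein and histone genes were higher in TE as sets, but not in each knockdown library alike. In siKrr1 A the small-subunit mean log2 CPM relative to controls was -0.01 in RNA and -0.05 in footprints. It was -0.13 and 0.08 in siKrr1 C and -0.33 and -0.21 in siKrr1 D. The histone mean was -0.17 in both assays in siKrr1 A. It was -0.07 and -0.04 in siKrr1 C and -0.30 and -0.09 in siKrr1 D. The large-subunit and TOP means in siKrr1 A were lower in RNA than in footprints. The camera adjusted p was 0.0164 for the small-subunit list (median 0.14) and the large-subunit list (median 0.05), and 0.00544 for the translation factors with TOP mRNAs (median 0.09) and the histones (median 0.07). With an estimated correlation the adjusted p was 0.838 for each of these 4 lists. With the lysate as a block these 4 lists stayed called (camera adjusted p from 0.00229 to 0.0149; adjusted p from 0.264 to 0.782 with an estimated correlation). Over the list alone, the block added 1 higher and 1 lower gene in the small-subunit and p53 lists and 1 higher gene in each of the large-subunit, histone, trophectoderm, heat shock and G2/M lists. Members stood at values such as 0.07 for Rps3, 0.12 for Rpl8 and 0.08 for Eef2, and 0 members were called over all genes (2 TOP genes were higher over the list alone, and 0 members of the other 3 lists). Without siKrr1 C the camera adjusted p was 0.703 for the small-subunit, 0.282 for the large-subunit and 0.0611 for the TOP list. It was 0.126 without Lipo for the small-subunit list, 0.0762 without siGFP for the large-subunit list, and 0.0612 without siGFP and 0.844 without siKrr1 D for the histones. The median was 0.09 for the large-subunit list without siKrr1 A, 0.06 for the TOP list without siNC and 0.02 for the histones without siKrr1 D. The other 20 lists tested were not called (camera adjusted p from 0.0609 for snoRNA hosts to 0.986), and 0 of their members were called over all genes or over the list alone. The snoRNA hosts were called without siGFP (0.0129) and without siKrr1 A (0.0363), and the G1/S list was called lower without siKrr1 D (0.0388). With an estimated correlation their adjusted p was then 0.923, 0.988 and 0.847. In TE the naive pluripotency and the large-subunit assembly lists had a median below 0 and a mean above 0, the heat shock list the opposite, and camera pointed down for glycolysis with a median and mean above 0.

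RNA and footprint changes were correlated. Across 13109 genes tested in both assays the log2 fold changes correlated with a Pearson r of 0.750 and a Spearman rho of 0.677, where genes are not independent replicates. Of the genes called higher, 241 were called in both assays where 12.7 are expected from independent lists, and of those called lower 176, where 7.89 are expected. 0 genes were called in opposite directions. Both assays share the lysates, so the lists are not independent. The other 9 ways of splitting the 6 lysates into 3 and 3 called 0 genes with edgeR in either assay and gave an r between 0.305 and 0.646. The covariance was 0.0836 for the real groups and 0.0125 to 0.0451 for the other splits. In each of the other splits both groups held knockdown lysates. The knockdown effect then adds to the spread within groups and enters r and the covariance. These splits are therefore no reference for data without an effect.

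**Figure D3:**
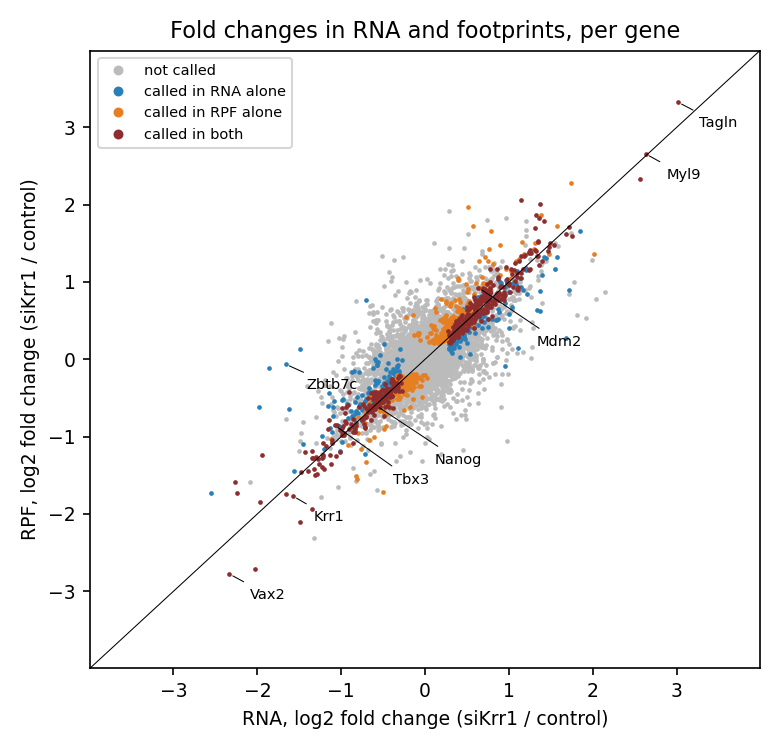
Log2 fold change of knockdown over control in RNA (horizontal axis) and in footprints (vertical axis), 1 point per gene, coloured by the assays in which it was called; the line marks equal change. Tagln (3.01 and 3.33) and Vax2 (-2.34 and -2.78) lie near the line, and Zbtb7c lies above it with -1.66 in RNA.

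Because Krr1 acts on the small subunit, small-subunit and large-subunit ribosomal protein genes were compared. The mean log2 CPM of the 33 small-subunit genes minus that of the 49 large-subunit genes was 0.83 ± 0.02 in controls and 0.88 ± 0.07 in knockdown RNA (SD, n = 3; exact permutation test, two-sided p = 0.4). In footprints it was 0.94 ± 0.04 and 0.98 ± 0.04 (exact permutation test, two-sided p = 0.4). For TE the difference was 0.11 ± 0.04 in controls and 0.10 ± 0.10 in knockdown (exact permutation test, two-sided p = 0.9). With 3 samples against 3 the smallest p this test can give is 0.1, so it could not have passed the threshold.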

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

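The tests of this part were chosen after the result was seen. In reads that the comparisons do not use, 3 values lay above those of the 3 controls of the same assay. The share of footprint alignments on no annotated feature was 60.4% in siKrr1 A and 63.3% in siKrr1 C, against at most 58.9% in the controls, while it was 57.8% in siKrr1 D. The group means were 58.2% ± 0.677 in controls and 60.5% ± 2.78 in knockdown (SD, n = 3; exact permutation test, two-sided p = 0.3). The share of RNA alignments on more than 1 gene was 0.206% in siKrr1 A, against at most 0.202% in the controls, but 0.196% in siKrr1 C and 0.187% in siKrr1 D, and the group mean was 0.201% in controls and 0.196% in knockdown (n = 3; exact permutation test, two-sided p = 0.4). Each was noted because a knockdown library exceeded the highest control. Values below the controls were not flagged by this rule. For example, the share of footprint alignments on more than 1 gene was 0.0649% in siKrr1 C, against 0.0706% in Lipo, the lowest control. No technical or biological explanation was tested for them, since the tables do not say where these reads lie.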

How the results depend on the processing

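None of these tests was chosen after the result was seen, and each alternative listed in the processing section was run. No gene called in RNA or footprints changed direction in any alternative. For genes without overlap between the groups this is a weak check, since they could hardly turn. The fall of Krr1 was called in all alternatives. For the other called named genes, 665 of 818 alternative values in RNA and 881 of 1058 in footprints kept the call, 153 and 177 lost it and 0 reversed; 21 of 59 and 29 of 76 genes kept it throughout. Most losses came without a control library (36, 34 and 32 genes in RNA without Lipo, siGFP and siNC). The splits of the 6 lysates into 3 and 3 number 10, too few for a share under 0.05: the real groups gave 674 calls in RNA, 806 in footprints and 0 in TE against at most 0 in the others, so that 1, 1 and 10 splits reached the real number. The other splits mix knockdown and control lysates in each group, which widens the spread within groups and works against calls. At these depths and 3 samples per group, 58% of simulated 1.5-fold changes were recovered in TE, against 76% in RNA and 85% in footprints. Depth was not varied. The simulated assays shared no lysate deviations and TE was fitted without the block. The TE figure is therefore not the power of the test on these paired lysates. The cause was not tested for the following.

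RNA calls (378 higher, 296 lower) were 672 and 533 with DESeq2, 582 and 477 without a filter, 466 lower with all 12 libraries in 1 fit, and 63 to 759 and 51 to 539 with a library left out. Footprint calls (450 and 356) were 784 and 616 without a filter, and 67 to 791 and 64 to 546 with a library left out. TE calls (0 and 0 with edgeR, 302 at an unadjusted p under 0.05) were 2 higher with DESeq2, 7 higher and 1 lower with the lysate as a replicate block, and 0 to 1 higher with a library left out; apart from the counts over single lists given in the report, the block changed no other call. Called lists (10 in RNA, 7 in footprints, 4 in TE) numbered 0, 0 and 0 with an estimated correlation, and TE lists 1 to 5 with a library left out. The correlation of RNA and footprint changes (0.750) was 0.867 for genes of at least 20 CPM and 0.677 as Spearman. The TE difference of small- and large-subunit genes turned to 0.016 for members of at least 5 CPM and ranged from -0.056 to 0.045 with a library left out.

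Changes of sign in named genes were all in genes not called. With library totals in place of TMM factors these were Bub1b in RNA (0.0093), Gnb2l1 in footprints (0.015) and Hist2h2bb (0.0051) and Esrrb (0.0012) in TE. TE Kdr was at -0.0064 with DESeq2 and -0.0061 with the block, and TE Trp53 at -0.00814 with limma-voom, -0.000703 with DESeq2 size factors and -0.0076 with the block. With a library left out the RNA ranges were Rps3 -0.11 to 0.031, Bub1b -0.045 to 0.023, Pkm -0.088 to 0.14 and Sox2 -0.024 to 0.091, and the footprint ranges Ncl -0.10 to 0.0027 and Gnb2l1 -0.049 to 0.033. The TE ranges were Emg1 -0.059 to 0.00056, Heatr1 -0.042 to 0.0072, Npm1 -0.11 to 0.047, Rpl4 -0.0088 to 0.099, Kdr -0.070 to 0.14, Apoe -0.048 to 0.035, Stmn2 -0.014 to 0.12, Krt18 -0.26 to 0.012, Mmp2 -0.11 to 0.038, Gtse1 -0.013 to 0.081, Hspa4 -0.073 to 0.019, Bst2 -0.15 to 0.030, Hist2h2bb -0.042 to 0.046, Hist1h1a -0.0019 to 0.10, Mcm5 -0.039 to 0.047, Top2a -0.15 to 0.021, Hmgcs1 -0.066 to 0.0046, Klf4 -0.14 to 0.067, Trp53 -0.10 to 0.067 and Cdkn1a -0.012 to 0.22. The called lists kept their call in 71, 54 and 29 alternative tests and lost it in 19, 9 and 11 in RNA, footprints and TE, the losses with an estimated correlation included; lists that gained a call are in the report.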

Other observations

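The tests of this part were chosen after the result was seen; the SRF and YAP lists were written after the rise of Tagln, Myl9, Cyr61, Ctgf and Thbs1 was seen and leave these genes out. Rn45s, the entry for 45S ribosomal RNA, in which the tables do not separate precursor from mature sequences, was lower in knockdown cells. In RNA it went from 8927 ± 2072 to 4757 ± 1619 CPM (SD, n = 3; log2 fold change -0.91 ± 0.21, edgeR adjusted p = 0.0359) and in footprints from 61149 ± 3642 to 45525 ± 3617 CPM (-0.43 ± 0.07, edgeR adjusted p = 0.00659). The RNA fall was small in siKrr1 C. Rn45s took 0.400%, 0.655% and 0.377% of the RNA gene counts in siKrr1 A, C and D, against 0.704% in Lipo, the lowest control. The highest knockdown library stood at 6612 CPM and the lowest control at 7100 CPM. The RNA libraries were depleted of ribosomal RNA, and for the footprint libraries no such step is described above. A lower recovery of structured noncoding RNAs in general is argued against by 9 others, Rmrp and Rpph1 among them, whose median log2 fold change was 0.044 in RNA and 0.17 in footprints, with 0 called by edgeR. Uneven removal of ribosomal RNA cannot be told apart from a lower level of these RNAs, since the highest control exceeded the lowest by a factor of 1.57 in RNA, against 1.88 between the group means (1.11 against 1.34 in footprints).

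Genes of the actin cytoskeleton rose beyond those that prompted the test. Of 24 genes of an SRF and actin cytoskeleton list, Cald1, Cnn2, Myh9, Tpm4, Vcl and Zyx rose in RNA and Tagln2 fell, and in footprints 9 of 25 rose and 1 fell. The median log2 fold change was 0.48 in RNA and 0.43 in footprints, and it was 0.73, 0.27 and 0.28 in siKrr1 A, C and D in RNA and 0.65, 0.13 and 0.37 in footprints. Of 19 YAP target genes, Amotl2, Gadd45a, Lats2 and Ptpn14 rose and Nt5e fell in RNA, and 3 rose in footprints. The median of the YAP list was 0.22, 0.05 and 0.25 in siKrr1 A, C and D in RNA and 0.27, 0.02 and 0.35 in footprints. These values are consistent with a higher SRF program (camera p = 2.00e-08 in RNA and 4.73e-09 in footprints) and a higher YAP program (camera p = 0.00405 and 0.0099), with the preset correlation. With an estimated correlation the camera p was 0.138 and 0.14 for the SRF list and 0.213 and 0.0935 for the YAP list. Neither list therefore passes camera without the preset value. The unadjusted fry p in RNA and footprints was 0.0631 and 0.0693 for the SRF list and 0.0812 and 0.0484 for the YAP list. Fibroblast-like cells in the knockdown cultures stay open as a source. Col1a1, Col1a2 and Col3a1 together went from 0.726 to 0.942 CPM in RNA, 1.3 times, while Tagln rose 8.16 times, a mean that siKrr1 A raised. By library, Tagln was at 18.8, 3.28 and 2.36 times the control mean in siKrr1 A, C and D and the collagens at 1.33, 1.11 and 1.45 times in RNA, so that in siKrr1 D the values lie close in this assay. In footprints they lie further apart, with Tagln at 23.1, 3.87 and 3.25 times and the collagens at 1.54, 0.854 and 1.35 times, where the control libraries alone ran from 0.722 to 1.18 times. The collagens had few counts in both assays, which keeps this open. Of the fibroblast list 2 of 14 genes rose in RNA and 3 of 15 in footprints, Tagln among them. The others included Col5a2 (by 1.36 on the log2 scale in RNA) and Bgn (by 1.59 in footprints). As a set the list was not called (camera adjusted p = 0.236 in RNA and 0.339 in footprints).

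The response was smallest in siKrr1 C. Over 673 genes called in RNA the median change in the called direction was 0.75, 0.43 and 0.65 in siKrr1 A, C and D, and siKrr1 C was the smallest in 73.1% of them; in footprints the medians were 0.64, 0.38 and 0.55 over 805 genes. Lower depth is argued against, since siKrr1 C held 1.2 times the counts of siKrr1 A in RNA and 1.10 times in footprints. The degree of Krr1 loss stays open: 37.3% of Krr1 RNA was left in siKrr1 C and 41.5% in siKrr1 D, and the order was opposite in footprints (37.5% and 31.4%). A share of cells without the knockdown also stays open. In RNA the median ratio of the change in siKrr1 C to that in siKrr1 A was 0.623, with quartiles of 0.449 and 0.814. The ratio of the Krr1 losses was 0.801. The genes were called in a fit that included siKrr1 C, so genes in which it responded little tend to be left out. This choice can raise the median ratio, which therefore cannot decide the question. Per the labels 3 different siRNAs were used, and effects of single siRNAs on other genes were not tested.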
